A study of Homo sapiens with 59 samples.

How the data were processed

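mRNA was sequenced from 59 libraries of SW1783 cells, taken after 24 h with 1 of 8 herbal extracts at 1 of 3 doses or with the DMSO vehicle. Per the labels, libraries were made with a directional kit and sequenced as 100 bp paired-end reads, and the authors list FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the genome builds hg38 and GRCh38, without the annotation release. The deposited values are expected counts per Ensembl gene, not normalized, for 60675 genes. They include fractions, and they were rounded before testing. Whole numbers made up 90.7% of all values and 75.85% of those above 0, as 61.47% of all values were 0. Gene names and positions came from GENCODE release 29, which holds 57055 of the identifiers. Total counts per library ran from 14084946 to 31688306, and 23857 genes had 0 counts in all libraries. Shares of counts rest on at least 14084946 counts per library, so counting error is small beside the spread between libraries.

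Groups were taken from the labels. The vehicle and 6 extracts with at least 2 libraries per dose entered 1 fit of 53 libraries in 19 groups with edgeR 4.0.16 under R 4.3.3 (TMM scaling, filterByExpr by group, robust quasi-likelihood F test), with 34 residual degrees of freedom and 17706 genes tested. The common dispersion was 0.0092, a coefficient of variation of 9.59%. The 27 comparisons were each extract and dose against the vehicle (18), high against low dose within an extract (6), and fresh against dried ginger at each dose (3), all two-sided. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. The 18 comparisons with the vehicle share its 3 libraries. The titles of all libraries, the vehicle included, name the same batch (C) and a second sequencing. The first part of the sample code, here called the label set, differs between the vehicle and the extracts. The labels do not call these sets batches, but any difference between them cannot be separated from the extracts.

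Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 32 lists with at least 5 tested members and all 27 comparisons together, and again with an estimated correlation. Members were also counted by the gene test, over all genes and adjusted over the list alone. Genes named in the text were those with the largest absolute log2 fold change among genes past the threshold, with a mean of at least 5 CPM in the higher group and all libraries of the groups apart (10 each way at the high dose, 5 each way elsewhere), and up to 6 members of each list by smallest p. Libraries of Coptidis Rhizoma and Zizyphi Fructus were compared with the vehicle mean as log2(CPM + 1), with TMM scaling over these libraries, among genes with at least 10 CPM in the higher value. Their list medians were ranked among 10000 random lists drawn from 20 bins of expression. These percentiles take the genes of a list as independent and describe 1 library, so they are not a test. CPM levels in that part and in the fit of 53 libraries come from separate scalings and differ slightly.

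Alternatives were DESeq2 1.42.0, other scaling factors, no filter on low counts, only the groups compared in the fit, the replicate number as a block, other pseudocounts, and leaving out each library. The comparisons, tests, gene lists, naming rule and these alternatives were fixed before the data were examined. Leaving out all extract libraries numbered 3, and the limit of 10 CPM in the library profiles, were chosen after seeing the data. The pipeline was tested on simulated data for high-dose Sayeok-tang and Bojungikgi-tang, where edgeR and DESeq2 were given known changes. Positive controls named in the design text are not among the libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were prepared with pandas 2.3.3 and NumPy 2.4.6.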

Results

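The data are RNA sequencing counts from 59 libraries of SW1783 cells, an established human astrocytoma line, each exposed for 24 h to a herbal extract or to the vehicle. The extracts were Sayeok-tang and Bojungikgi-tang, which are multi-herb decoctions extracted in water, and ethanol extracts of Zingiberis Rhizoma Recens (fresh ginger), Zingiberis Rhizoma (dried ginger), Pinelliae Tuber, Scutellariae Radix, Coptidis Rhizoma and Zizyphi Fructus (jujube). Each of the 8 extracts was given at 3 doses that differed by a factor of 5. The high, medium and low doses were 500, 100 and 20 µg/mL, except for Scutellariae Radix at 230, 46 and 9.2 µg/mL and Coptidis Rhizoma at 14, 2.8 and 0.56 µg/mL. Vehicle and most extract doses had 3 libraries. Bojungikgi-tang had 2 at each dose, dried ginger had 2 at the high dose, and Coptidis Rhizoma and Zizyphi Fructus had 1 at each dose. The labels give 0.1% DMSO for the vehicle, while the text on the study design gives 2%. Total counts per library ran from 14084946 to 31688306, and those of the vehicle libraries from 17492540 to 21697189. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only a spread between libraries. In the main fit this spread was estimated over all 53 libraries of the fit, not only those compared. Unlike libraries in other groups can therefore widen it and lower the counts, so a count of 0 does not show that groups are alike.

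Libraries of 1 label often had unlike profiles. Over the 2000 most variable genes with a mean of at least 10 CPM, libraries 1 and 2 of a label had a median Pearson correlation of 0.582 across genes, which are not independent replicates. Library 1 was closest to library 2 of its own label in 8 of 15 groups, and library 2 to library 1 in 9 of 15. The extract libraries numbered 3 often differed: their median correlation was -0.11 with library 1 and 0.088 with library 2 of the same label. Their closest match was their own label in 0 of 14 groups among libraries numbered 1 and in 2 of 17 among those numbered 2. This was not so everywhere: vehicle library 3 had a correlation of 0.774 with the mean of vehicle libraries 1 and 2, libraries 2 and 3 of high-dose Bojungikgi-tang had 0.851, and at the medium dose of Scutellariae Radix libraries 2 and 3 had 0.778 and libraries 1 and 2 -0.156. The library labelled low-dose Sayeok-tang 3 had a correlation of 0.984 with libraries 1 and 2 of medium-dose Pinelliae Tuber and of -0.652 with its own label. For the library labelled high-dose Scutellariae Radix 3, the closest were libraries 1 and 2 of low-dose dried ginger, at 0.963. The library labelled medium-dose fresh ginger 3 was closest to high-dose Sayeok-tang, at 0.914. All libraries were analysed under their labels, and counts without the extract libraries numbered 3 are given beside the main ones as an alternative chosen after seeing the data.

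**Figure D1:**
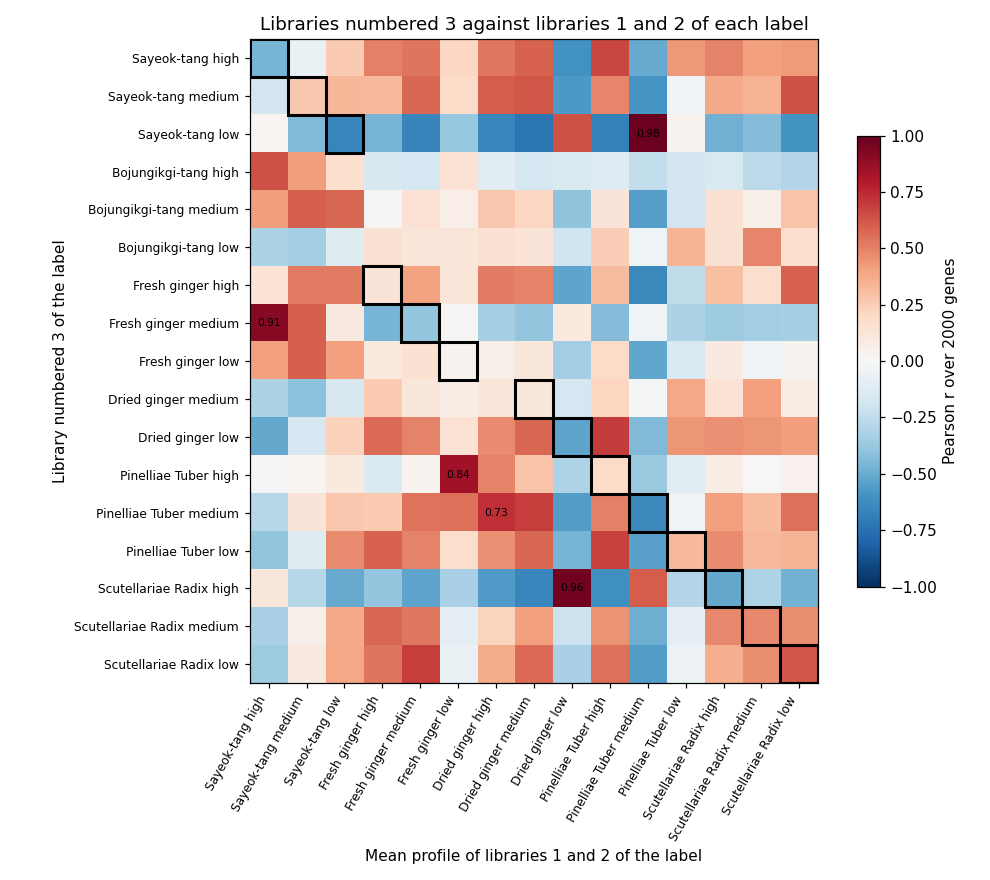
Pearson correlation across 2000 genes between each extract library numbered 3 (vertical axis) and the mean profile of libraries 1 and 2 of each label (horizontal axis), with the library's own label outlined in black. Values above 0.7 are printed, and the highest is 0.98 for low-dose Sayeok-tang 3 against medium-dose Pinelliae Tuber.

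Sayeok-tang was compared with the vehicle at each dose to find the genes that respond to it. CXCL8, a neutrophil-attracting chemokine, had 64.2 CPM in each of libraries 1 and 2 at the high dose, 4.28 CPM in library 3 and 5.06 ± 0.0867 CPM (SD, n = 3) in the vehicle. Its log2 fold change over the 3 libraries was 3.11 (SE 0.80, edgeR adjusted p = 0.0518). Of the 25 measured members of the NF-kB and inflammatory cytokine list, 1 rose over all genes (SOD2, a mitochondrial superoxide dismutase, log2 1.32, SE 0.34, adjusted p = 0.0494 in edgeR) and 16 rose adjusted over the list alone. The list median was 1.27 (limma camera adjusted p = 8.63e-11, and adjusted p = 0.984 with an estimated correlation). CEBPB, a transcription factor of the acute-phase response, rose from 32.96 ± 3.40 to 61.0 ± 8.26 CPM (SD, n = 3 each; log2 0.88, SE 0.17), and NFKBIZ, an NF-kB cofactor, rose by 1.10 on the log2 scale (SE 0.21). FERMT2, an integrin activator, fell by 0.34 (SE 0.07), and PDE5A, which degrades cyclic GMP, fell by 0.40 (SE 0.09). In the list of cytosolic ribosomal proteins 4 of 28 members fell over all genes and 8 adjusted over the list alone (camera adjusted p = 5.96e-07, and adjusted p = 0.998 with an estimated correlation). RPS28 fell by 0.46 (SE 0.08) and RPL18 had a log2 fold change of -0.29 (SE 0.06). Over all 17706 genes tested by edgeR, 86 rose and 56 fell at the high dose.

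At the medium dose of Sayeok-tang 14 genes rose and 3 fell, among them BCL6, a transcriptional repressor, with a log2 fold change of 0.45 (SE 0.08, n = 3 each). Over the 3 libraries labelled low dose 309 genes rose and 199 fell (244 and 284 with total counts only). Library 3 of these had a correlation of -0.652 with libraries 1 and 2 and of 0.984 with medium-dose Pinelliae Tuber. The group means below may therefore rest on library 3. CPT1B, a fatty acid importer of mitochondria, rose by 1.29 on the log2 scale (SE 0.26) and AMT, a glycine cleavage enzyme, by 1.38 (SE 0.29). Both varied widely at this dose, with 7.19 ± 3.12 CPM for CPT1B and 6.04 ± 4.05 CPM for AMT (SD, n = 3). MAML2, a Notch coactivator, fell by 0.59 (SE 0.17). Of 24 integrated stress response (ATF4) targets, 1 rose over all genes (CEBPB, log2 0.79, SE 0.17) and 21 adjusted over the list alone, with a list median of 1.21 (limma camera adjusted p = 5.93e-06, and adjusted p = 0.998 with an estimated correlation). CHAC1, a glutathione-degrading enzyme of this list, had 53.02 CPM in library 3 against 3.22 and 4.31 CPM in libraries 1 and 2. Of 20 endoplasmic reticulum chaperones, 1 rose over all genes (PDIA3, log2 0.52, SE 0.15) and 18 adjusted over the list alone (camera adjusted p = 1.92e-05, and adjusted p = 0.998 with an estimated correlation). EdgeR called 21, 53 and 45 genes without vehicle libraries 1, 2 and 3 in turn and 16, 24 and 377 genes without Sayeok-tang libraries 1, 2 and 3 in turn, all at the high dose. EdgeR called 5, 5 and 4 genes without vehicle libraries 1, 2 and 3 in turn and 5, 6 and 10 genes without Sayeok-tang libraries 1, 2 and 3 in turn, all at the medium dose. EdgeR called 49, 128 and 118 genes without vehicle libraries 1, 2 and 3 in turn and 1817, 1349 and 132 genes without Sayeok-tang libraries 1, 2 and 3 in turn, all at the low dose. Without the extract libraries numbered 3, the counts at the high, medium and low doses were 2487, 631 and 952, and with only the compared groups in the fit 529, 637 and 0.

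Between the high and the low dose of Sayeok-tang edgeR called 0 genes at n = 3 each, with 1776 at an unadjusted p under 0.05 and 4 called by DESeq2. BIRC3, an inhibitor of apoptosis, had a log2 difference of 1.58 (SE 0.37, adjusted p = 0.401) and CXCL8 one of 2.47 (SE 0.76, adjusted p = 0.418). In the NF-kB list 0 of 25 members rose over all genes and 12 adjusted over the list alone (camera adjusted p = 1.36e-11, and adjusted p = 0.984 with an estimated correlation). Leaving out libraries gave 0, 0 and 44 genes without high-dose libraries 1, 2 and 3 in turn and 0, 0 and 0 genes without low-dose libraries 1, 2 and 3 in turn. Without the libraries numbered 3 the count was 786.

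Bojungikgi-tang at the high dose raised inflammatory genes in both of its libraries. CXCL8 (ENSG00000169429, GRCh38 chromosome 4, 73740506 to 73743716) rose from 5.06 ± 0.0867 (SD, n = 3) to 79.3 ± 4.11 CPM (SD, n = 2), a log2 fold change of 3.97 (SE 0.85, edgeR adjusted p = 0.0126). IL6, a cytokine of the acute-phase response, rose from 4.71 ± 0.497 to 23.8 ± 1.05 CPM, and ICAM1, a leukocyte adhesion receptor, from 52.4 ± 2.26 to 174 ± 3.18 CPM. The cytokine IL11 rose by 1.40 on the log2 scale (SE 0.32), CXCL1, another neutrophil chemokine, by 4.26 (SE 0.90), and NFKBIA, the inhibitor of NF-kB, by 1.02 (SE 0.21). Of 25 NF-kB and inflammatory genes, 10 rose over all genes and 21 adjusted over the list alone. The list median was 1.499 (limma camera adjusted p = 2.26e-22, and adjusted p = 0.506 with an estimated correlation). In the type I interferon list 1 of 25 members rose over all genes (MX1, an antiviral GTPase, log2 0.84, SE 0.16) and 3 adjusted over the list alone (camera adjusted p = 9.02e-07, and adjusted p = 0.934 with an estimated correlation). ITGB4, an integrin of hemidesmosomes, fell by 0.78 (SE 0.15), KCNMA1, a calcium-activated potassium channel, by 0.52 (SE 0.11) and PDE5A by 0.54 (SE 0.10).

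Over all genes, 108 rose and 67 fell at the high dose of Bojungikgi-tang, 18 rose and 4 fell at the medium dose, and 23 rose and 9 fell at the low dose. With the medium dose, CXCL8 had 23.1 and 23.6 CPM and CEBPB rose by 0.86 on the log2 scale (SE 0.18, n = 2 against 3). In the NF-kB list 0 members passed over all genes or over the list alone at this dose (median 0.69, camera adjusted p = 3.69e-06, and adjusted p = 0.998 with an estimated correlation). KIFC2, a kinesin, rose at the low dose by 0.55 (SE 0.11) and DPM3, a mannosyltransferase subunit, fell by 0.56 (SE 0.10). EdgeR called 45, 57 and 70 genes without vehicle libraries 1, 2 and 3 in turn and 27 and 6 genes without Bojungikgi-tang libraries 2 and 3 in turn, all at the high dose. EdgeR called 4, 8 and 12 genes without vehicle libraries 1, 2 and 3 in turn and 4 and 5 genes without Bojungikgi-tang libraries 2 and 3 in turn, all at the medium dose. EdgeR called 4, 6 and 7 genes without vehicle libraries 1, 2 and 3 in turn and 18 and 0 genes without Bojungikgi-tang libraries 2 and 3 in turn, all at the low dose. Without the extract libraries numbered 3, which leaves 1 library per dose assumed to vary like the other groups, the counts at the high, medium and low doses were 669, 85 and 12, and with only the compared groups in the fit 2589, 1488 and 427.

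Between the high and the low dose of Bojungikgi-tang, 2 genes rose and 0 fell by edgeR, with 1013 at an unadjusted p under 0.05 and 12 called by DESeq2. With only the compared groups in the fit 170 rose and 133 fell. The low count therefore depends on the libraries from which the spread was estimated, and does not show that the doses act alike. TFPI2, a secreted protease inhibitor, was at 162 ± 4.15 CPM against 90.3 ± 9.19 CPM (SD, n = 2 each), and SERPINE2, an inhibitor of thrombin and urokinase, was at 889.5 ± 17.7 against 694 ± 26.4 CPM. Of the 25 NF-kB genes, 0 rose over all genes and 21 adjusted over the list alone (median 1.42, camera adjusted p = 3.29e-32, and adjusted p = 0.28 with an estimated correlation). CXCL8 had a log2 difference of 3.56 (SE 0.95, adjusted p = 0.269). Leaving out libraries gave 0 and 0 genes without high-dose libraries 2 and 3 in turn and 1 and 0 genes without low-dose libraries 2 and 3 in turn, and without those numbered 3 the count was 100.

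**Figure D2:**
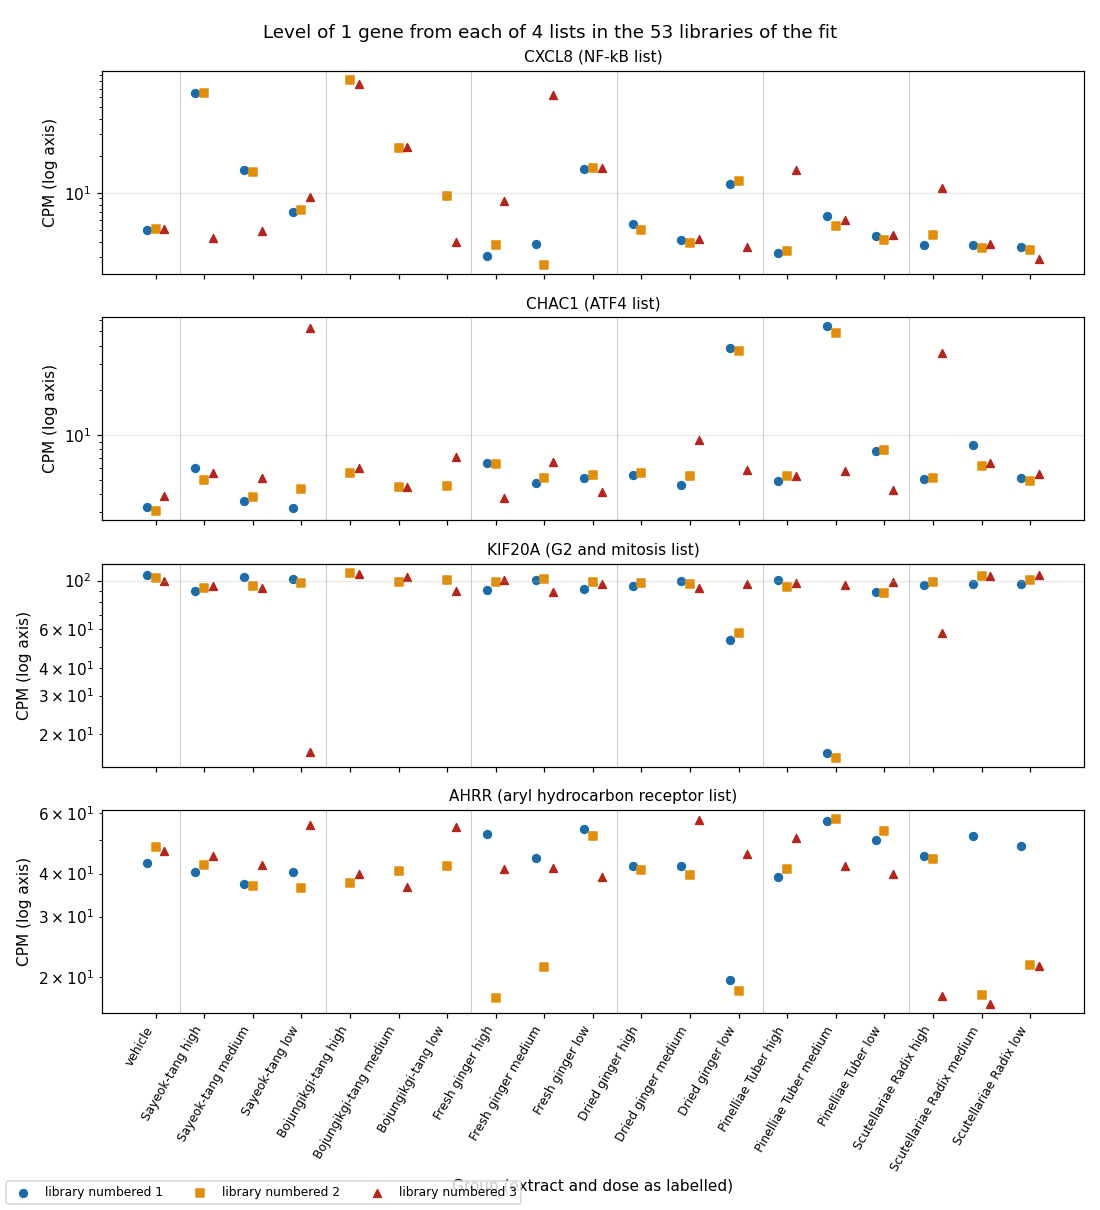
Level of CXCL8, CHAC1, KIF20A and AHRR in CPM on log axes (vertical) in each library of the vehicle and 6 extracts (horizontal, by labelled extract and dose), with 1 point per library and its shape and colour giving the library number. CXCL8 stands at 64.2 CPM in libraries 1 and 2 of high-dose Sayeok-tang against 4.28 CPM in library 3, and KIF20A at 16.5 and 15.7 CPM in libraries 1 and 2 of medium-dose Pinelliae Tuber against 95.6 CPM in library 3.

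HSPA1B, an inducible heat shock chaperone, rose at the high dose of fresh ginger from 83.1 ± 6.67 to 119 ± 14.9 CPM (SD, n = 3 each; log2 0.52, SE 0.11, edgeR adjusted p = 0.0210). UBA7, the activating enzyme for ISG15, rose by 0.52 on the log2 scale (SE 0.07), OSBPL7, an oxysterol-binding protein, by 0.73 (SE 0.14), and BCL6 by 0.48 (SE 0.08). CAMSAP1, which binds microtubule minus ends, fell by 0.24 (SE 0.05) and RPS28 by 0.47 (SE 0.08). UBA7 and BCL6 were each called in 16 of the 18 comparisons with the vehicle, OSBPL7 in 11, CAMSAP1 in 12 and RPS28 in 18. The changes of these genes are therefore not particular to fresh ginger. Of 18 heat shock genes, 1 rose over all genes and 2 adjusted over the list alone at the high dose (limma camera adjusted p = 0.031, and adjusted p = 0.998 with an estimated correlation), and at the medium dose HSPA1B rose by 0.52 (SE 0.11). CCN1, a matricellular YAP target, rose at the low dose from 200 ± 12.4 to 348 ± 86.6 CPM, and MRPL53, a mitochondrial ribosomal protein, fell by 0.52 (SE 0.10). CXCL8 was at 15.7, 15.8 and 15.8 CPM in the low-dose libraries, and at 3.80, 2.60 and 62.7 CPM in medium-dose libraries 1, 2 and 3. Over all genes, 29 rose and 8 fell at the high dose, 45 rose and 12 fell at the medium dose, and 21 rose and 19 fell at the low dose (50 and 55 with DESeq2).

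For fresh ginger against the vehicle, the counts without the extract libraries numbered 3 were 718, 423 and 1632 at the high, medium and low doses, and with only the compared groups in the fit 498, 237 and 351. EdgeR called 6, 8 and 8 genes without vehicle libraries 1, 2 and 3 in turn and 15, 10 and 29 genes without fresh ginger libraries 1, 2 and 3 in turn, all at the high dose. EdgeR called 15, 17 and 15 genes without vehicle libraries 1, 2 and 3 in turn and 15, 41 and 16 genes without fresh ginger libraries 1, 2 and 3 in turn, all at the medium dose. EdgeR called 3, 6 and 11 genes without vehicle libraries 1, 2 and 3 in turn and 5, 6 and 243 genes without fresh ginger libraries 1, 2 and 3 in turn, all at the low dose. Between the high and low doses edgeR called 0 genes, with 983 at an unadjusted p under 0.05 and 0 by DESeq2. In the NF-kB list 0 of 25 members passed over all genes or over the list alone in that comparison (median -0.43, camera adjusted p = 1.1e-06, and adjusted p = 0.998 with an estimated correlation). Leaving out libraries gave 0, 0 and 0 genes without high-dose libraries 1, 2 and 3 in turn and 0, 0 and 33 genes without low-dose libraries 1, 2 and 3 in turn, and without those numbered 3 the count was 953.

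Stress and lipid genes rose on average over the 3 libraries labelled low-dose dried ginger. Library 3 stood apart, with correlations of -0.473 and -0.559 with libraries 1 and 2. CHAC1 and SCD were far lower in library 3 than in libraries 1 and 2. CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519) rose from 3.41 ± 0.436 to 27.1 ± 18.4 CPM (SD, n = 3 each; log2 3.00, SE 0.80, edgeR adjusted p = 0.0236), with 38.4, 37.1 and 5.84 CPM in libraries 1, 2 and 3. ATF4, the transcription factor of the integrated stress response, rose from 102 ± 3.23 to 248 ± 116 CPM, and ATF3, a stress-induced repressor, by 2.22 on the log2 scale (SE 0.68). Of 24 ATF4 targets 6 rose over all genes and 19 adjusted over the list alone (median 1.22, limma camera adjusted p = 9.9e-08, and adjusted p = 0.998 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose by 1.29 (SE 0.29) and SREBF1, which drives fatty acid synthesis genes, by 0.91 (SE 0.23), with 4 of 16 members of the fatty acid synthesis list rising over all genes and 10 over the list alone (camera adjusted p = 0.000558, and adjusted p = 0.998 with an estimated correlation). ABCA1, a cholesterol exporter, rose by 1.41 (SE 0.36) among 4 of 11 liver X receptor targets that rose over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0105, and adjusted p = 0.984 with an estimated correlation). Of 24 immediate early genes 7 rose and 1 fell over all genes, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000178, and adjusted p = 0.998 with an estimated correlation), including JUN with a log2 fold change of 0.57 (SE 0.10) and EGR1 with 1.28 (SE 0.25). In the extracellular matrix list 3 of 27 members fell over all genes and 11 adjusted over the list alone (camera adjusted p = 2.86e-08, and adjusted p = 0.998 with an estimated correlation), among them COL4A1, a basement membrane collagen, which fell by 0.32 (SE 0.09).

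Over all genes, 586 rose and 452 fell at the low dose of dried ginger, 69 rose and 34 fell at the medium dose (n = 3), and 35 rose and 7 fell at the high dose (n = 2). The lowest dose had the most calls. Its libraries 1 and 2 resembled the library labelled high-dose Scutellariae Radix 3 (correlation of 0.963 with their mean). Which of these labels are right cannot be told. CCN1 rose at the high dose from 200 ± 12.4 to 342 ± 1.09 CPM and MT-ND3, a subunit of respiratory complex I, by 0.80 on the log2 scale (SE 0.18). BCL6 rose at the medium dose by 0.65 (SE 0.08) and SAMD4A, an RNA-binding repressor of translation, fell by 0.78 (SE 0.18). EdgeR called 7, 7 and 25 genes without vehicle libraries 1, 2 and 3 in turn and 5 and 2 genes without dried ginger libraries 1 and 2 in turn, all at the high dose. EdgeR called 10, 38 and 23 genes without vehicle libraries 1, 2 and 3 in turn and 33, 55 and 17 genes without dried ginger libraries 1, 2 and 3 in turn, all at the medium dose. EdgeR called 209, 402 and 507 genes without vehicle libraries 1, 2 and 3 in turn and 73, 300 and 2387 genes without dried ginger libraries 1, 2 and 3 in turn, all at the low dose. Without the extract libraries numbered 3, the counts at the high, medium and low doses were 526, 372 and 5513, and with only the compared groups in the fit 949, 1286 and 388. Between the high and low doses edgeR called 0 genes, with 2109 at an unadjusted p under 0.05 and 25 by DESeq2. Leaving out libraries gave 0 and 1 genes without high-dose libraries 1 and 2 in turn and 0, 0 and 744 genes without low-dose libraries 1, 2 and 3 in turn, and without those numbered 3 the count was 4183. In that comparison 13 of 25 cholesterol genes were lower at the high dose adjusted over the list alone and 0 over all genes (camera adjusted p = 3.9e-08, and adjusted p = 0.984 with an estimated correlation).

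Fresh and dried ginger come from the rhizome of the same plant and were compared at matched doses. Lipid genes were lower with fresh than with dried ginger at the low dose. SCD was at 221 ± 29.4 CPM with fresh and 664 ± 354 CPM with dried ginger (SD, n = 3 each; log2 -1.58, SE 0.29, edgeR adjusted p = 0.0122), and SREBF1 at 35.5 ± 6.20 and 91.2 ± 38.5 CPM. ABCA1 fell by 1.66 on the log2 scale (SE 0.36), INSIG1, a sterol sensor of the endoplasmic reticulum, by 1.03 (SE 0.23), and FASN, the fatty acid synthase, by 0.55 (SE 0.12). Of 25 cholesterol genes 5 fell over all genes and 15 adjusted over the list alone (limma camera adjusted p = 1.36e-11, and adjusted p = 0.819 with an estimated correlation). In the fatty acid list 5 of 16 fell and 1 rose over all genes, and 12 fell and 1 rose adjusted over the list alone (camera adjusted p = 4.66e-08, and adjusted p = 0.588 with an estimated correlation). PLAU, the urokinase plasminogen activator, was higher with fresh ginger by 0.71 (SE 0.15), and TGFA, a ligand of the EGF receptor, by 0.69 (SE 0.13). Over all genes 50 were higher and 68 lower with fresh ginger, and 0 differed with only the compared groups in the fit. SCD was at 887 and 848 CPM in dried ginger libraries 1 and 2, and at 256 CPM in library 3.

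At the low dose the fresh against dried comparison called 3, 1 and 384 genes without fresh ginger libraries 1, 2 and 3 in turn and 0, 1 and 1259 genes without dried ginger libraries 1, 2 and 3 in turn by edgeR, and 4620 without both libraries numbered 3. At the high dose (n = 3 and 2) edgeR called 0 genes, with 521 at an unadjusted p under 0.05 and 0 by DESeq2. At the medium dose (n = 3 each) edgeR called 0 genes, with 465 at an unadjusted p under 0.05 and 0 by DESeq2. Both unadjusted counts are under a share of 0.05 of the 17706 genes tested. CXCL8 had a log2 difference of 2.50 (SE 0.79, adjusted p = 1.00) at the medium dose, which became -0.35 without fresh ginger library 3. There, 7 of 25 NF-kB genes were higher with fresh ginger adjusted over the list alone and 0 over all genes (camera adjusted p = 6.32e-08, and adjusted p = 0.998 with an estimated correlation). A count of 0 does not show that both extracts act alike.

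At the medium dose of Pinelliae Tuber all 24 measured ATF4 targets rose, over all genes and over the list alone (median 1.81, limma camera adjusted p = 6.2e-10, and adjusted p = 0.998 with an estimated correlation). CHAC1 rose from 3.41 ± 0.436 to 36.1 ± 26.5 CPM (SD, n = 3 each; log2 3.40, SE 0.80, edgeR adjusted p = 0.00371). DDIT3, a pro-apoptotic transcription factor, rose by 2.77 (SE 0.62) and ASNS, the asparagine synthetase, by 2.59 (SE 0.58). Of 20 endoplasmic reticulum chaperones 19 rose over all genes and 19 over the list alone (camera adjusted p = 1.04e-08, and adjusted p = 0.998 with an estimated correlation), with HYOU1 at a log2 fold change of 1.25 (SE 0.26) and MANF at 1.12 (SE 0.25). Of 28 G2 and mitosis genes 26 fell over all genes and 27 over the list alone (median -0.84, camera adjusted p = 2.67e-13, and adjusted p = 0.998 with an estimated correlation). KIF20A, a mitotic kinesin, fell by 1.25 (SE 0.41) and CCNB1, the mitotic cyclin, by 0.88 (SE 0.25). Of 26 S phase genes 21 fell and 1 rose over all genes, and 24 fell and 1 rose over the list alone (camera adjusted p = 4.87e-10, and adjusted p = 0.998 with an estimated correlation). The helicase subunit MCM4 fell by 0.60 (SE 0.15), and CDC6, which loads it, rose by 0.27 (SE 0.07). Libraries 1 and 2 carried these values: KIF20A was at 16.5, 15.7 and 95.6 CPM and DDIT3 at 220, 231 and 22.9 CPM in libraries 1, 2 and 3. The library labelled low-dose Sayeok-tang 3 had a correlation of 0.984 with the mean of libraries 1 and 2. EdgeR called 4795 genes at this dose against 79 at the high dose. Which of these labels are right cannot be told, so the profile may not belong to this extract and dose.

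Other gene groups also changed on average over the libraries labelled medium-dose Pinelliae Tuber. Here too library 3 stood apart, with correlations of -0.645 and -0.637 with libraries 1 and 2. Of 24 NRF2 targets 15 rose and 1 fell over all genes, and 19 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 3.25e-05, and adjusted p = 0.998 with an estimated correlation). FTL and FTH1, the ferritin chains, rose by 2.00 (SE 0.40) and 1.86 (SE 0.38) on the log2 scale. Of 28 lysosome and autophagy genes 17 rose and 2 fell over all genes, and 18 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000325, and adjusted p = 0.998 with an estimated correlation). Of 20 tubulin and actin genes 9 fell over all genes and 13 adjusted over the list alone (camera adjusted p = 1.23e-05, and adjusted p = 0.998 with an estimated correlation). Of 8 astrocyte markers 5 fell over all genes and 6 adjusted over the list alone (camera adjusted p = 0.00215, and adjusted p = 0.998 with an estimated correlation), including SLC1A3, a glutamate transporter, which fell by 0.81 (SE 0.27), and NES, the intermediate filament nestin, by 0.68 (SE 0.25). CCL2, a monocyte chemokine, fell from 27.01 ± 2.61 to 8.08 ± 9.28 CPM.

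Over all genes, 2667 rose and 2128 fell at the medium dose of Pinelliae Tuber (2309 and 2493 with total counts only), 50 rose and 29 fell at the high dose, and 246 rose and 240 fell at the low dose (285 and 401 with DESeq2). EGR1, an immediate early transcription factor, rose at the high dose from 20.1 ± 2.04 to 43.3 ± 6.55 CPM (SD, n = 3 each), CCN1 by 0.79 on the log2 scale (SE 0.14) and MT-ND3 by 0.81 (SE 0.17). UQCRQ, a subunit of respiratory complex III, fell by 0.32 (SE 0.08). With the low dose OSBPL7 rose by 0.77 (SE 0.14) and SAMD4A fell by 0.82 (SE 0.18). EdgeR called 12, 35 and 35 genes without vehicle libraries 1, 2 and 3 in turn and 26, 28 and 31 genes without Pinelliae Tuber libraries 1, 2 and 3 in turn, all at the high dose. EdgeR called 2957, 3059 and 3277 genes without vehicle libraries 1, 2 and 3 in turn and 572, 769 and 7901 genes without Pinelliae Tuber libraries 1, 2 and 3 in turn, all at the medium dose. EdgeR called 76, 207 and 232 genes without vehicle libraries 1, 2 and 3 in turn and 69, 374 and 236 genes without Pinelliae Tuber libraries 1, 2 and 3 in turn, all at the low dose. Without the extract libraries numbered 3, the counts at the high, medium and low doses were 590, 8882 and 2006, and with only the compared groups in the fit 572, 0 and 2320. Between the high and low doses edgeR called 0 genes, with 722 at an unadjusted p under 0.05 and 0 by DESeq2. The 722 are under a share of 0.05 of the 17706 genes tested. Leaving out libraries gave 0, 0 and 0 genes without high-dose libraries 1, 2 and 3 in turn and 0, 0 and 0 genes without low-dose libraries 1, 2 and 3 in turn, and without those numbered 3 the count was 8.

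Scutellariae Radix at the medium dose lowered PTGS2, the inducible prostaglandin synthase, from 108 ± 2.55 to 53.4 ± 4.67 CPM (SD, n = 3 each; log2 -1.02, SE 0.26, edgeR adjusted p = 0.0291). ABCB1, a drug efflux pump, fell by 0.58 on the log2 scale (SE 0.15) and EGR1 rose by 0.90 (SE 0.25). In the aryl hydrocarbon receptor list 0 of 12 members passed over all genes or over the list alone (median -0.49, limma camera adjusted p = 0.0112, and adjusted p = 0.998 with an estimated correlation). AHRR, the repressor of that receptor, was at 51.5, 17.7 and 16.7 CPM in libraries 1, 2 and 3 against 45.7 CPM on average in the vehicle. Libraries 1 and 2 of this dose had a correlation of -0.156. At the high dose library 3 had -0.511 with the mean of libraries 1 and 2, and 0.963 with low-dose dried ginger. List medians and some group means may therefore rest on 1 or 2 libraries. PIM1, a survival kinase, rose at the high dose by 0.77 (SE 0.13), BCL6 by 0.65 (SE 0.08) and EGR1 by 1.04 (SE 0.25). The ubiquitin ligase NEDD4 fell there by 0.33 (SE 0.05). ATF4 targets had a median of 0.80 at the high dose, where 0 of 24 rose over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000857, and adjusted p = 0.998 with an estimated correlation). CHAC1 was at 5.03, 5.08 and 35.7 CPM in these libraries (log2 2.20, SE 0.81, adjusted p = 0.221). PIK3C2B, a phosphoinositide kinase, rose at the low dose by 0.70 (SE 0.17) and ADAMTS1, a secreted metalloproteinase, fell by 0.51 (SE 0.12).

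Over all genes, 46 rose and 28 fell at the high dose of Scutellariae Radix, 174 rose and 153 fell at the medium dose, and 58 rose and 49 fell at the low dose. With DESeq2 more fell than rose at the medium dose (188 up, 240 down) and the low dose (83 up, 91 down). EdgeR called 21, 21 and 35 genes without vehicle libraries 1, 2 and 3 in turn and 54, 85 and 22 genes without Scutellariae Radix libraries 1, 2 and 3 in turn, all at the high dose. EdgeR called 30, 113 and 139 genes without vehicle libraries 1, 2 and 3 in turn and 90, 124 and 162 genes without Scutellariae Radix libraries 1, 2 and 3 in turn, all at the medium dose. EdgeR called 21, 31 and 22 genes without vehicle libraries 1, 2 and 3 in turn and 38, 32 and 15 genes without Scutellariae Radix libraries 1, 2 and 3 in turn, all at the low dose. Without the extract libraries numbered 3, the counts at the high, medium and low doses were 498, 1592 and 597, and with only the compared groups in the fit 1, 1255 and 1365. Between the high and low doses edgeR called 0 genes, with 568 at an unadjusted p under 0.05 and 0 by DESeq2. The 568 are under a share of 0.05 of the 17706 genes tested. Leaving out libraries gave 0, 0 and 0 genes without high-dose libraries 1, 2 and 3 in turn and 1, 0 and 0 genes without low-dose libraries 1, 2 and 3 in turn, and without those numbered 3 the count was 0.

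Coptidis Rhizoma had 1 library per dose, so its values carry no test and no replicate error. GDF15, a stress-induced cytokine, was at 497 CPM at the high dose against 3.76 ± 0.384 CPM (SD, n = 3) in the vehicle, a difference of 6.71 in log2(CPM + 1), with 37.0 CPM at the medium and 4.32 CPM at the low dose. DDIT3 was at 547, 74.5 and 21.9 CPM at the high, medium and low doses against 22.2 ± 0.718 CPM, and TRIB3, a pseudokinase of the stress response, at 414, 112 and 17.7 CPM against 19.2 ± 0.869 CPM. The thyroid hormone deiodinase DIO2 was at 2.35 CPM at the high dose against 61.3 ± 1.05 CPM, and SLC1A3 at 2.68 against 33.1 ± 1.57 CPM. The median difference of ATF4 targets was 1.99, 1.33 and 0.00 at the high, medium and low doses, at percentiles 100, 100 and 58.8 of 10000 random lists of like expression. In the same order endoplasmic reticulum chaperones had medians of 0.92, 0.29 and 0.04, and lysosome and autophagy genes of 0.73, 0.24 and 0.08. The median of G2 and mitosis genes was -1.54, -0.33 and -0.105, and that of S phase genes -1.22, -0.48 and -0.04. At the high dose 854 genes were higher and 734 lower than the vehicle mean by at least 1 log2 unit, against 51 and 7 at the medium and 10 and 2 at the low dose. Each vehicle library set in this way against the mean of the other 2 vehicle libraries gave at most 4 genes higher and 3 lower. The mitochondrial ribosomal RNA MT-RNR1 was at 11300, 20310 and 1969 CPM at the high, medium and low doses against 663 ± 21.4 CPM.

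**Figure D3:**
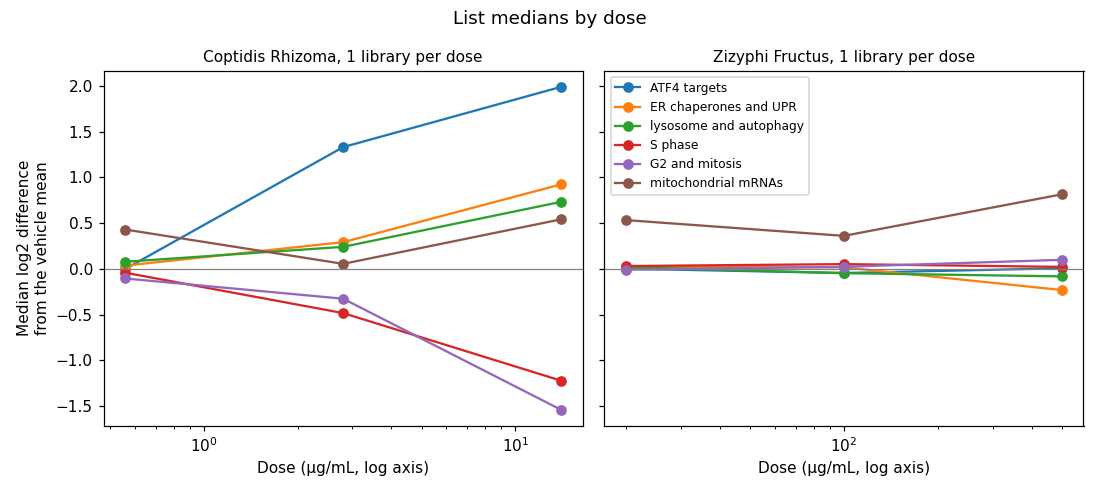
Median difference from the vehicle mean in log2(CPM + 1) (vertical axis) for 6 gene lists against dose in µg/mL on a log axis (horizontal), with 1 point per library and no error bars, since each dose has 1 library. For Coptidis Rhizoma the ATF4 targets go from 0.00 at the low dose to 1.99 at the high dose and the G2 and mitosis genes reach -1.54.

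Zizyphi Fructus had 1 library per dose, so no test was made. TXNIP, a thioredoxin inhibitor induced by glucose, was at 199.5 CPM at the high dose against 8.37 ± 0.941 CPM (SD, n = 3), a difference of 4.42 in log2(CPM + 1), with 14.3 CPM at the medium and 9.77 CPM at the low dose. Its relative ARRDC4 was at 25.95 CPM against 5.82 ± 0.529 CPM, and EGR1 at 58.1 against 19.2 ± 1.81 CPM. FAM13B was at 29.8 against 77.8 ± 0.882 CPM, and the metallothionein MT1E at 5.85 against 13.9 ± 0.887 CPM. RGPD5, which has near-identical paralogs that make its counts uncertain, was at 4.70 against 26.1 ± 4.44 CPM. At the high, medium and low doses mitochondrially encoded genes had median differences of 0.815, 0.36 and 0.53, each at percentile 100, and immediate early genes of 0.21, 0.17 and 0.08, at percentiles 100, 100 and 97.5. Endoplasmic reticulum chaperones had -0.23 at percentile 0, and then 0.017 and 0.021 at percentiles 90.5 and 83.3. The percentiles take the genes of a list as independent and are not a test. At the high dose 14 genes were higher and 8 lower by at least 1 log2 unit, against 6 and 6 at the medium and 2 and 2 at the low dose.

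Some genes passed the test in most comparisons with the vehicle, whatever the extract. TMEM160, a mitochondrial membrane protein, CLK2, a splicing kinase, RPS28 and the pseudogene AL157400.5 were called in 18 of 18. Their median log2 fold changes were 0.93, 0.52, -0.47 and 4.54. All 18 calls of a gene rest on the same vehicle libraries, where TMEM160 was at 2.951, 6.75 and 10.09 CPM, and library 1 of low-dose Sayeok-tang, at 9.789 CPM, lay below the highest of these. In all, 46 genes were called in at least 9 of these comparisons, 32 up and 14 down, and made up 7.02% of all calls. Among them are genes named above under an extract: BCL6 and UBA7 (16 of 18 each), KIFC2 (13), CAMSAP1 (12), OSBPL7 and NEDD4 (11 each). Their changes are therefore not particular to the extract under which they were named. Outside these 46, EGR1, CCN1 and MT-ND3 were named under several extracts. CCN1 and MT-ND3 were also above the vehicle mean in every Coptidis Rhizoma and Zizyphi Fructus library. HSPA1B was above it in every Zizyphi Fructus library but below it at the high and medium doses of Coptidis Rhizoma. FMC1-LUC7L2, COMMD3-BMI1, MSH5-SAPCD1 and JMJD7-PLA2G4B, which were named at several doses, are readthrough transcripts that share reads with their parent genes, and LIMS4, HSPD1P11, RPSAP15 and GBAP1 have close relatives, so their values are uncertain. The mitochondrially encoded list was called as higher in 17 of the 18 comparisons, with medians over all 18 from 0.16 to 0.59 on the log2 scale, and its lowest value with an estimated correlation was adjusted p = 0.586 in limma camera. Mitochondrial genes took 5.65 ± 0.342% of counts in the vehicle (SD, n = 3), and 54 of 56 extract libraries lay above every vehicle library, up to 15.8% for medium-dose Coptidis Rhizoma. Cytosolic ribosomal proteins were called as lower in 12 of the 18 comparisons, and their lowest value was adjusted p = 0.998 with an estimated correlation. The calls between high and low doses shared 0 genes for any pair of extracts by edgeR, where 2 genes were called in all.

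Across all 32 lists and 27 comparisons limma camera called 200 of 864 tests with the preset correlation and 0 with an estimated correlation. The latter was estimated from deviations around the label means of all 53 libraries. Libraries unlike others of their label can raise it where list members vary together, and it was not estimated without them. The 0 therefore does not decide whether lists changed. Among markers of cell types, VIM, an intermediate filament of astrocytes and other cells, was at 4028 ± 209 CPM in the vehicle (SD, n = 3), and GFAP, the filament of mature astrocytes, at 0.132 ± 0.0869 CPM. Of the 15 epithelial markers 4 passed 1 CPM in any library, with KRT7 up to 656 CPM. Neuron markers passed 1 CPM for 5 of 12, with TUBB3 up to 114 CPM, and leukocyte markers for 6 of 13, with CD68, a lysosomal glycoprotein, up to 327 CPM. Hepatocyte markers passed 1 CPM for 4 of 15, with the fibrinogen chain FGG up to 26.1 CPM. The epithelial, neuron and leukocyte lists were called in 0 of the 18 comparisons with the vehicle by limma camera.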

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

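The comparison of fresh with dried ginger was planned, and the other tests in this part were chosen only after the results were seen. The difference between fresh and dried ginger was tested gene by gene in edgeR at each dose, with 118 genes at the low dose, and 0 there with only the compared groups in the fit. Higher with fresh ginger were PLAU (log2 0.71), TGFA (0.69), CPM, a carboxypeptidase (0.60), LPXN (0.57) and DMRTA2 (0.50). Lower with fresh ginger were SCD (log2 -1.58), SREBF1 (-1.36), NFATC2 (-1.02), JUND (-0.98) and AMDHD2 (-0.75). Without library 3 of dried ginger the count was 1259, and without library 1 of dried ginger it was 0.

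With 3 libraries against 3 there are 10 splits, so a share under 0.05 cannot be reached for any comparison. Against the vehicle, the real split gave the highest count, and 1 of 10 splits reached it. The real count and the highest of the other splits were 142 and 0 for high-dose Sayeok-tang, 17 and 0 for medium-dose Sayeok-tang, 508 and 1 for low-dose Sayeok-tang, 37 and 0 for high-dose fresh ginger, 57 and 0 for medium-dose fresh ginger, 40 and 1 for low-dose fresh ginger, 103 and 0 for medium-dose dried ginger, 1038 and 3 for low-dose dried ginger, 79 and 0 for high-dose Pinelliae Tuber, 4795 and 4503 for medium-dose Pinelliae Tuber, 486 and 0 for low-dose Pinelliae Tuber, 74 and 0 for high-dose Scutellariae Radix, 327 and 0 for medium-dose Scutellariae Radix and 107 and 0 for low-dose Scutellariae Radix. For high against low dose all 10 splits reached the real count of 0, and the highest other count was 287 for Sayeok-tang and 0 for fresh ginger, Pinelliae Tuber and Scutellariae Radix. Fresh against dried ginger at the medium dose had a real count of 0, reached by all 10 splits, and a highest other of 1. At the low dose 2 of 10 splits reached the real count of 118, and the highest other was 261. The 4503, 287 and 261 genes in splits that mix the groups, for medium-dose Pinelliae Tuber against the vehicle, high against low dose of Sayeok-tang and fresh against dried ginger at the low dose, point to a structure of the samples that the groups do not explain.

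Most extract libraries numbered 3 lay closest to another label. Differences in depth are argued against by thinning every library to the lowest total. Among libraries numbered 2, the closest was then still that of the own label for 2 of 17 libraries numbered 3. Libraries 1 and 2 matched each other as often as before. Mislabelled samples may account for part of the matches with another label. A match does not tell which of the libraries would carry the wrong label. Of 17 extract libraries numbered 3, 2 were nearest a library of their own label and 15 a library of another label. Of all 53 libraries of the fit, 13 were nearest their own label, so libraries numbered 1 and 2 often lay nearest another label too. Among the 15, the label with the closest mean of libraries 1 and 2 was for 10 a label where these had a correlation of at least 0.5 with each other. For 5 of these 10 the mean correlation with those 2 single libraries was at least that between them. This test was set after seeing the data, and extracts with like responses could give the same correlations. Medium-dose fresh ginger 3, high- and medium-dose Pinelliae Tuber 3 and high-dose Scutellariae Radix 3 matched labels equally many places earlier in the sample codes. Low-dose Sayeok-tang 3, also among the 5, matched a later label. Like responses alone give no reason for an equal step. The order was looked at after the matches, was not tested, and other libraries numbered 3 did not follow it. Libraries 1 and 2 of a label had a median correlation of 0.582, while library 3 had -0.11 with library 1. Variation that is alike between all cultures would not give this difference. Responses that vary between cultures still stay open, since the labels do not say whether libraries numbered 3 were handled apart. No library was assigned to another group.

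The 46 genes called against the vehicle in at least 9 comparisons may come from the vehicle libraries rather than from the extracts. GC content is argued against as the whole cause, because 47 genes met the same rule after a GC correction of each library, 38 of them shared, with a median absolute log2 fold change of 0.41 before and 0.39 after. A part played by GC stays open, since the 32 higher genes had a median GC content of 59.4% and the 14 lower genes 51.6%, against 48.2% for all genes. Chance values shared through the vehicle gave 0 such genes in 4 simulations, which excludes nothing since it rests on simulated settings. The titles place the vehicle and all extracts in the same batch. A difference in handling that sets the vehicle libraries apart still cannot be told apart from an effect of all extracts. No extract shares a label set, the first part of the sample code, with the vehicle. The median ratio of low-dose to high-dose change was 1.01, which decides nothing, since genes called at most doses are likely to have a ratio near 1 by how they were chosen.

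Mitochondrial ribosomal RNA was high in the Coptidis Rhizoma libraries, with MT-RNR1 higher than the vehicle by 4.09, 4.93 and 1.57 log2 units at the high, medium and low doses. More mitochondrial RNA of all kinds is argued against at the high and medium doses, where the 13 mitochondrially encoded mRNAs had a median difference of 0.54 and 0.055. At the low dose that median was 0.43, which leaves this explanation open. Weaker poly(A) selection may contribute and stays open, because only 3 small structural RNA genes could be measured, with medians of at most -1.13. An effect of the extract itself was not tested apart from these.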

How the results depend on the processing

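Most of these alternatives were fixed in advance, and only leaving out all extract libraries numbered 3 was chosen after seeing the data; the cause was not tested except where stated. With DESeq2 the counts beyond 1.5 times those of edgeR were 232 for high-dose Sayeok-tang, 44 for medium-dose Sayeok-tang, 835 for low-dose Sayeok-tang, 37 for medium-dose Bojungikgi-tang, 55 for low-dose Bojungikgi-tang, 71 for high-dose fresh ginger, 96 for medium-dose fresh ginger, 105 for low-dose fresh ginger, 67 for high-dose dried ginger, 194 for medium-dose dried ginger, 163 for high-dose Pinelliae Tuber, 165 for high-dose Scutellariae Radix, 174 for low-dose Scutellariae Radix, 4 for high against low dose of Sayeok-tang, 12 for high against low dose of Bojungikgi-tang, 25 for high against low dose of dried ginger and 382 for fresh against dried ginger at the low dose. With no filter on low counts more genes are tested and adjusted for, and the counts were 62 for high-dose Sayeok-tang, 7 for medium-dose Sayeok-tang, 240 for low-dose Sayeok-tang, 79 for high-dose Bojungikgi-tang, 10 for medium-dose Bojungikgi-tang, 18 for low-dose Bojungikgi-tang, 17 for high-dose fresh ginger, 23 for medium-dose fresh ginger, 25 for low-dose fresh ginger, 25 for high-dose dried ginger, 49 for medium-dose dried ginger, 446 for low-dose dried ginger, 35 for high-dose Pinelliae Tuber, 3143 for medium-dose Pinelliae Tuber, 193 for low-dose Pinelliae Tuber, 29 for high-dose Scutellariae Radix, 121 for medium-dose Scutellariae Radix, 38 for low-dose Scutellariae Radix and 19 for fresh against dried ginger at the low dose. With only the compared groups in the fit, the spread is estimated from fewer libraries, and the counts were 529 for high-dose Sayeok-tang, 637 for medium-dose Sayeok-tang, 0 for low-dose Sayeok-tang, 2589 for high-dose Bojungikgi-tang, 1488 for medium-dose Bojungikgi-tang, 427 for low-dose Bojungikgi-tang, 498 for high-dose fresh ginger, 237 for medium-dose fresh ginger, 351 for low-dose fresh ginger, 949 for high-dose dried ginger, 1286 for medium-dose dried ginger, 388 for low-dose dried ginger, 572 for high-dose Pinelliae Tuber, 0 for medium-dose Pinelliae Tuber, 2320 for low-dose Pinelliae Tuber, 1 for high-dose Scutellariae Radix, 1255 for medium-dose Scutellariae Radix, 1365 for low-dose Scutellariae Radix, 303 for high against low dose of Bojungikgi-tang, 11 for fresh against dried ginger at the high dose and 0 for fresh against dried ginger at the low dose. With total counts only, the count was 13 for medium-dose Bojungikgi-tang, and the share of called genes that rose went from 81.8 to 69.2% there, from 63.3 to 51.2% for high-dose Pinelliae Tuber, from 50.6 to 39.4% for low-dose Pinelliae Tuber, from 60.8 to 46.2% for low-dose Sayeok-tang and from 42.4 to 23.9% for fresh against dried ginger at the low dose. The larger direction changed from rising to falling in several settings. With DESeq2 this gave 50 up and 55 down for low-dose fresh ginger, 285 up and 401 down for low-dose Pinelliae Tuber, 188 up and 240 down for medium-dose Scutellariae Radix, and 83 up and 91 down for low-dose Scutellariae Radix. With RLE factors this gave 234 up and 290 down for low-dose Pinelliae Tuber. With total counts only this gave 244 up and 284 down for low-dose Sayeok-tang, 2309 up and 2493 down for medium-dose Pinelliae Tuber, 202 up and 311 down for low-dose Pinelliae Tuber, and 54 up and 56 down for low-dose Scutellariae Radix. With only the compared groups this gave 252 up and 277 down for high-dose Sayeok-tang, 302 up and 335 down for medium-dose Sayeok-tang, 1181 up and 1408 down for high-dose Bojungikgi-tang, 734 up and 754 down for medium-dose Bojungikgi-tang, 210 up and 217 down for low-dose Bojungikgi-tang, 160 up and 191 down for low-dose fresh ginger, 1053 up and 1267 down for low-dose Pinelliae Tuber, 595 up and 660 down for medium-dose Scutellariae Radix, and 682 up and 683 down for low-dose Scutellariae Radix. Leaving out the extract libraries numbered 3 it gave 1222 up and 1265 down for high-dose Sayeok-tang, 308 up and 323 down for medium-dose Sayeok-tang, 438 up and 514 down for low-dose Sayeok-tang, 785 up and 847 down for low-dose fresh ginger, 998 up and 1008 down for low-dose Pinelliae Tuber, 237 up and 261 down for high-dose Scutellariae Radix, and 749 up and 843 down for medium-dose Scutellariae Radix. For low-dose Pinelliae Tuber it was 36 up and 40 down without vehicle library 1, and 163 up and 211 down without its own library 2. Fresh against dried ginger at the low dose turned the other way with no filter (11 up and 8 down) and without fresh ginger library 1 (2 up and 1 down), fresh ginger library 2 (1 up and 0 down) or dried ginger library 2 (1 up and 0 down). Without the extract libraries numbered 3, which leaves fewer libraries, the counts were 2487 for high-dose Sayeok-tang, 631 for medium-dose Sayeok-tang, 952 for low-dose Sayeok-tang, 669 for high-dose Bojungikgi-tang, 85 for medium-dose Bojungikgi-tang, 12 for low-dose Bojungikgi-tang, 718 for high-dose fresh ginger, 423 for medium-dose fresh ginger, 1632 for low-dose fresh ginger, 526 for high-dose dried ginger, 372 for medium-dose dried ginger, 5513 for low-dose dried ginger, 590 for high-dose Pinelliae Tuber, 8882 for medium-dose Pinelliae Tuber, 2006 for low-dose Pinelliae Tuber, 498 for high-dose Scutellariae Radix, 1592 for medium-dose Scutellariae Radix, 597 for low-dose Scutellariae Radix, 786 for high against low dose of Sayeok-tang, 100 for high against low dose of Bojungikgi-tang, 953 for high against low dose of fresh ginger, 4183 for high against low dose of dried ginger, 8 for high against low dose of Pinelliae Tuber, 19 for fresh against dried ginger at the high dose and 4620 for fresh against dried ginger at the low dose; list calls went from 200 to 304 and genes shared between high-against-low comparisons from 0 to 310. The 310 is a sum over 15 pairs of extracts in which a gene can count in several pairs, and independent calls would give 241.5. The pairs differ: Sayeok-tang and Bojungikgi-tang shared 55 up and 31 down against 1.31 and 0.856 for independent calls, Sayeok-tang and dried ginger 30 and 9 against 42.4 and 49.5, and fresh and dried ginger 92 and 43 against 62.6 and 48.4. CXCL8 between fresh and dried ginger at the medium dose went from 2.50 to -0.32 without these libraries, and leaving out each library in turn gave -0.35 (without fresh ginger library 3) to 3.02. Leaving out each library in turn, where a group left with 1 library is assumed to vary like the others, gave lowest and highest counts of 16 and 377 for high-dose Sayeok-tang, 4 and 10 for medium-dose Sayeok-tang, 49 and 1817 for low-dose Sayeok-tang, 6 and 70 for high-dose Bojungikgi-tang, 4 and 12 for medium-dose Bojungikgi-tang, 0 and 18 for low-dose Bojungikgi-tang, 6 and 29 for high-dose fresh ginger, 15 and 41 for medium-dose fresh ginger, 3 and 243 for low-dose fresh ginger, 2 and 25 for high-dose dried ginger, 10 and 55 for medium-dose dried ginger, 73 and 2387 for low-dose dried ginger, 12 and 35 for high-dose Pinelliae Tuber, 572 and 7901 for medium-dose Pinelliae Tuber, 69 and 374 for low-dose Pinelliae Tuber, 21 and 85 for high-dose Scutellariae Radix, 30 and 162 for medium-dose Scutellariae Radix, 15 and 38 for low-dose Scutellariae Radix, 0 and 44 for high against low dose of Sayeok-tang, 0 and 1 for high against low dose of Bojungikgi-tang, 0 and 33 for high against low dose of fresh ginger, 0 and 744 for high against low dose of dried ginger, 0 and 1 for high against low dose of Scutellariae Radix and 0 and 1259 for fresh against dried ginger at the low dose. List calls were 168, 147 and 291 without libraries 1, 2 and 3, and 0 with an estimated correlation. Of the 304 list calls without the extract libraries numbered 3, 147 were among the main 200, and 143 of them had the same direction. For high-dose Zizyphi Fructus the 22 genes became 13 with a pseudocount of 5 and 55 with a limit of 1 CPM. The library numbers gave no support for pairing: deviations of same-numbered libraries had correlations from -0.09 to 0.068 across genes, which are not independent replicates. With the replicate block the counts stayed within 1.5 times, for example 4647 for medium-dose Pinelliae Tuber. Of 302 values of named genes, 291 kept their direction and side of the threshold with DESeq2, 298 with RLE factors, 285 with total counts only, 268 with the replicate block, 186 with no filter and 169 with only the compared groups. This held for 265 without the extract libraries numbered 3, while 26 became weaker, 10 stronger and 1 reversed. Leaving out each library in turn gave several refits per named value, and the next counts are over all these refits. In 771 the direction and side of the threshold were kept, 960 became weaker, 12 stronger and 1 reversed. Becoming weaker, which means losing the call, was thus the most frequent outcome.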

Other observations

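None of the tests in this part was chosen after a result was seen. In simulated data with the design of high-dose Sayeok-tang, edgeR recovered 76% of genes changed by a factor of 2 and 91% of those changed by a factor of 4, with 4 false calls among 17482 genes. With the design of high-dose Bojungikgi-tang these were 73% and 84%, with 7 false calls. The simulation gave a gene the same dispersion in all groups and drew the libraries of a group alike. Real libraries of a label were often unlike, so these rates may not hold for the real data. The NF-kB list, with all members raised by a factor of 2 at high-dose Pinelliae Tuber, had an adjusted p of 6.41e-31 in limma camera. It was the only list of 32 called. Each gene was drawn independently, so the preset correlation was met by design. The simulation therefore cannot show how the list test does with correlated genes.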
